A study of Mus musculus with 6 samples.

How the data were processed

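RNA was taken from bone marrow cells of 6 mice with secondary transplants of a Hoxa9 and Meis1 leukaemia, 3 with lymphoid leukaemia cells (Lym, mice 62, 63 and 87) and 3 with Lin-, Kit-positive progenitor cells (Lin-, mice 56, 57 and 91). Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a stranded total RNA kit for picogram input from 2 ng of RNA (1 ng for Lym mouse 62) with 12 PCR cycles, and 38-base reads came from an Illumina NextSeq instrument. Groups were taken from the labels, which give neither a pairing between the mice nor a batch.

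Per the submitters' processing notes, the authors used bcl2fastq, Trim Galore 0.6.4, STAR 2.6.1d, featureCounts 1.6.4 and DESeq2 on genome build GRCm38.p6, and neither the DESeq2 version nor the annotation release is stated there. The deposited table holds 55401 genes, of which 987 have no gene name and 23797 no read in any library. The deposited values per library are a normalized signal, gene counts divided by 1 size factor per library by the authors. Every such value was a whole multiple of its library's step (tolerance 0.01, checked on values up to 10000), so whole reads were recovered from them. Per the file headers the table also holds the authors' log2 fold change, its standard error, a Wald score and the authors' p-value with its adjusted form. Set against the library values, that fold change is positive where Lin- is higher. It was taken as shrunken toward 0 because a DESeq2 refit with a prior gave the same values within 0.00021. Signs were turned to Lym minus Lin- here. Of the gene identifiers, 54349 matched GENCODE M21 by version and coordinates. Positions are those of GRCm38. The notes do not state whether counting used the strand or how reads shared between near-identical or overlapping genes were split, so values of such genes are uncertain.

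Recovered reads came to 18537700 to 22634286 per library. A floor of 3 reads is given per library, and floors cover counting error only, since PCR copies were not told apart.

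Differences were computed with limma 3.58.1 (R 4.3.3) on log2(normalized count + 2), with the trend option, over 14273 genes with at least 10 normalized counts in at least 3 libraries. Calls were made at an adjusted p of 0.05 by Benjamini-Hochberg. The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test. Because the deposited values are normalized, limma took its place, and edgeR 4.0.16 with TMM on the recovered reads became an added alternative. DESeq2 1.42.0 and limma-voom were run on the recovered reads. 32 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 5 members passed the filter, with Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were alternatives. Principal components were taken over the 500 most variable genes. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used to read the table and draw the figures.

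The genes named were set by a rule fixed before the data were examined. It took the 10 highest and 10 lowest genes past the threshold, with a mean of at least 5 CPM and groups that do not overlap, leaving out receptor segments and unnamed gene models. It also took Hoxa9, Meis1, Kit, Ptprc, Cd34, Itgam, Il7r and Flt3, up to 4 called members of each list or otherwise its 2 most abundant members, and exceptions to a list's direction. Some genes under this rule are not reported here. With 0 limma calls the first part named no gene, so it was applied to the calls of the authors' deposited table. That step, the list members among those calls, 12 further genes given in the report and the genes named only in the closing section were chosen after their values were seen.

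The fits were tested on simulated data with the measured spread and 200 changed genes among 14239 tested by limma. At 2-, 4-, 8- and 16-fold changes limma recovered 32%, 88%, 98% and 96% of 50 genes each, with 18 false calls of 175. edgeR, over 14318 genes, recovered 34%, 86%, 98% and 98% with 13 false calls of 171. DESeq2, over 29079 genes, recovered 50%, 90%, 98% and 96% with 52 false calls of 219. The simulated genes varied independently, and no simulated library was set apart from its group as that of Lym mouse 87 was. These shares therefore do not show what the real fits missed. In the real data Aff3, with a ratio of means of 6.118, had a limma adjusted p of 0.139. Alternatives covered the scaling, the tool, the filter on low values, the pseudocount, library weights, the depth and leaving out each mouse in turn.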

Results

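Gene expression was measured by total RNA sequencing in leukaemic bone marrow cells of 6 mice, each of which had received a secondary transplant of a leukaemia driven by the homeobox genes Hoxa9 and Meis1. 3 libraries, from mice 62, 63 and 87, hold lymphoid leukaemia cells (Lym) of mice that had received lymphoid cells. The other 3, from mice 56, 57 and 91, hold lineage-negative, Kit-positive progenitor cells (Lin-) of mice that had received such cells. Every mouse gave 1 library, so the spread within a group is a spread between animals. No donor leukaemia is listed for each mouse here, so whether mice share a donor is not known. The tests treat each mouse as independent. Reads assigned to genes came to 18734083, 18537700 and 21332571 in the Lym libraries of mice 62, 63 and 87, and to 22422344, 22634286 and 19988561 in the Lin- libraries of mice 56, 57 and 91. A floor of 3 reads equalled a normalized count of 3.36, 3.36 and 2.86 in the Lym libraries and of 2.65, 2.64 and 3.09 in the Lin- libraries, which covers counting error only. The series asks how the lymphoid cells of this myeloid leukaemia stand to its Lin- progenitor cells, and 1 comparison follows from the labels, Lym minus Lin-. Fold changes below are differences of log2(normalized count + 2) with their standard errors, and adjusted p-values are Benjamini-Hochberg values from limma over the 14273 genes tested unless another tool is named.

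On the first principal component the libraries of mice 62 and 63 stood apart from the other 4, and the Lym library of mouse 87 lay among the Lin- libraries. Over the 500 most variable genes the first principal component held 61.8% of the variance. Its scores were -52.5 for Lym mouse 62, -32.9 for Lym mouse 63, 26.4 for Lym mouse 87, and 18.7, 3.86 and 36.4 for Lin- mice 56, 57 and 91. On component 2 Lym mice 62 and 63 lay at opposite ends, at -21.4 and 20.9. Lym mouse 87, at -14.4, lay there below the Lin- libraries (-7.04 to 13.9). On component 3 it was at 15.4, above the Lin- libraries (-22.2 to 6). Across genes, Pearson correlations of log2 values were 0.970 to 0.973 between Lin- libraries and 0.927 to 0.958 between Lym libraries. Lym mouse 87 correlated at 0.965 to 0.979 with the 3 Lin- libraries, above its values of 0.927 and 0.948 with Lym mice 62 and 63. Lym mouse 63 correlated at 0.961 with Lin- mouse 57, above its value of 0.958 with Lym mouse 62. These correlations are across genes, which are not independent replicates, and carry no test.

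**Figure D1:**
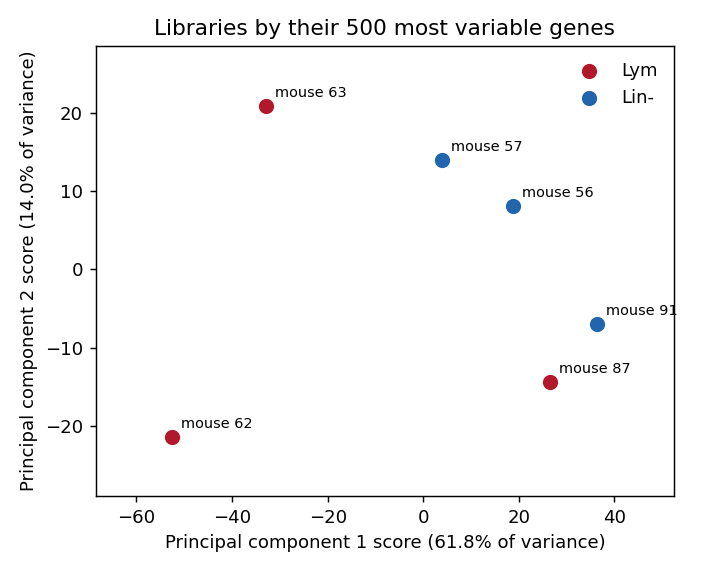
Scores of the 6 libraries on the first 2 principal components of log2(normalized count + 2) over the 500 most variable genes, with the percent of variance on each axis and the mouse number beside each point. Lym mice 62 and 63 have negative scores on component 1, at -52.5 and -32.9, and Lym mouse 87, at 26.4, lies there between Lin- mice 56 and 91. On component 2 Lym mouse 87, at -14.4, lies below the Lin- libraries.

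Aff3 and Epb41l4b were higher in all 3 Lym mice than in any Lin- mouse, and Clec7a and Igf2r were higher in all 3 Lin- mice than in any Lym mouse. The rule for naming these genes required groups that do not overlap. Aff3, a nuclear protein first known from lymphoid cells (chromosome 1, 38177326 to 38664955 in GRCm38), stood at normalized counts of 4865, 4689 and 2039 in Lym mice 62, 63 and 87 and 577, 829 and 489 in Lin- mice 56, 57 and 91, a log2 fold change of 2.54 ± 0.34 (SE, limma adjusted p = 0.139). Epb41l4b, a FERM-domain protein (chromosome 4, 56991972 to 57143437), was at 406 ± 38.3 in Lym against 73.1 ± 21.7 in Lin- (SD, n = 3 each), a log2 fold change of 2.48 ± 0.28 (limma adjusted p = 0.0749). Clec7a, the beta-glucan receptor Dectin-1 (chromosome 6, 129461591 to 129472779), was at 144 ± 29.1 in Lym against 651 ± 106 in Lin- (SD, n = 3 each), with a log2 fold change of -2.17 ± 0.22 (limma adjusted p = 0.0681). Igf2r, the cation-independent mannose 6-phosphate receptor (chromosome 17, 12682406 to 12769664), was at 644 ± 222 against 2782 ± 849, with a log2 fold change of -2.13 ± 0.29 (limma adjusted p = 0.139). No gene passed an adjusted p of 0.05 in limma, where 1459 had an unadjusted p under 0.05, 850 higher and 609 lower in Lym. The count was also 0 with edgeR, where 1442 genes had an unadjusted p under 0.05, and with limma-voom, where 1355 did. DESeq2 put 215 genes past the threshold, 177 higher and 38 lower in Lym. The value ranges of the groups were apart in 2223 of the 14273 genes, or 15.6%, where a single gene has a chance of 10%. Genes vary together, so the share can lie far from 10% without a group difference, and it carries no test. Splitting off Lym mice 62 and 63 with Lin- mouse 57 gave 3155 genes with an unadjusted limma p under 0.05, against 1459 here.

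The number of calls turned on the Lym library of mouse 87. Without it limma put 1348 genes past the threshold, 765 higher and 583 lower in Lym, edgeR 1286 and DESeq2 2080. That mouse lay among the Lin- libraries on the first principal component, so leaving it out favours calls. These counts are no separate support for a group difference. Leaving out any other mouse gave 0 or 1 in limma, with 1 without Lin- mouse 91. DESeq2 fell from 215 to 65 without Lym mouse 62, to 53 without Lym mouse 63, to 53 without Lin- mouse 56, to 105 without Lin- mouse 57 and to 54 without Lin- mouse 91.

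The authors' deposited table, a DESeq2 comparison of the same libraries, held 101 genes at an adjusted p under 0.05, 81 higher and 20 lower in Lym. All 101 were among the 215 DESeq2 calls, and 95 of them had groups that did not overlap. DESeq2 with a prior and without filtering, run here on the recovered reads, also gave 101 calls. Its log2 fold changes differed from the deposited ones by at most 0.00021. The same tool and libraries gave both sets, so the overlap is no separate support. Of the 99 that passed the low-value filter, 99 had the same direction and an unadjusted p under 0.05 in limma. Without Lym mouse 87, 92 of the 101 were limma calls.

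Besides Aff3 and Epb41l4b, 8 genes were among the 10 highest in Lym among the calls of the authors' deposited table with at least 5 CPM and groups that did not overlap. Fads2, a fatty acid desaturase, was at 1654, 1094 and 407 in Lym mice 62, 63 and 87 against 193, 136 and 146 in Lin- mice 56, 57 and 91. Il17rb, a receptor subunit for interleukin-25, was at 461, 129 and 96.2 against 28.2, 22 and 17.5. The GTPase-activating protein Arhgap32 was at 585, 320 and 76.2 against 15.9, 22 and 33.0. Zfpm1, a cofactor of GATA transcription factors, was at 1209, 557 and 314 against 224, 171 and 134. Kcng1, a potassium channel subunit, was at 1237 ± 323 against 437.5 ± 46.9, and Ldlrad4 at 264 ± 63.5 against 73.5 ± 30.6 (SD, n = 3 each). Fam129a was at 588 ± 273 against 146 ± 25.1, and Dennd5b at 262 ± 201 against 47.9 ± 8.04. In each of these 8 genes the Lym library of mouse 87 had the lowest Lym value. That it lay above all 3 Lin- libraries was set by the rule that the groups do not overlap.

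Besides Clec7a and Igf2r, 8 genes were among the 10 highest in Lin- by the same rule. Clec5a, a C-type lectin receptor of myeloid cells, was at 11.2, 41.4 and 74.3 in Lym mice 62, 63 and 87 against 368, 256 and 218 in Lin- mice 56, 57 and 91. Galc, the lysosomal galactosylceramidase, was at 111 ± 53.3 against 439 ± 40.8 (SD, n = 3 each). Lrp1, an endocytic receptor, was at 1494 ± 344 against 3699 ± 1046. Protein kinase C beta (Prkcb) was at 227 ± 149 against 679 ± 146.5, and the sulfide quinone oxidoreductase Sqor at 57.4 ± 52.9 against 225 ± 52.0. Kcnip3 was at 139 ± 92.5 against 434 ± 83.3, Sh3bp5 at 104 ± 66.6 against 349 ± 70.1 and Tmem273 at 94.6 ± 9.67 against 263 ± 53.9. The low-affinity Fc receptor Fcgr3, a list member among the authors' calls but outside those 10, was at 1366 ± 51.2 against 2311 ± 167.5.

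**Figure D2:**
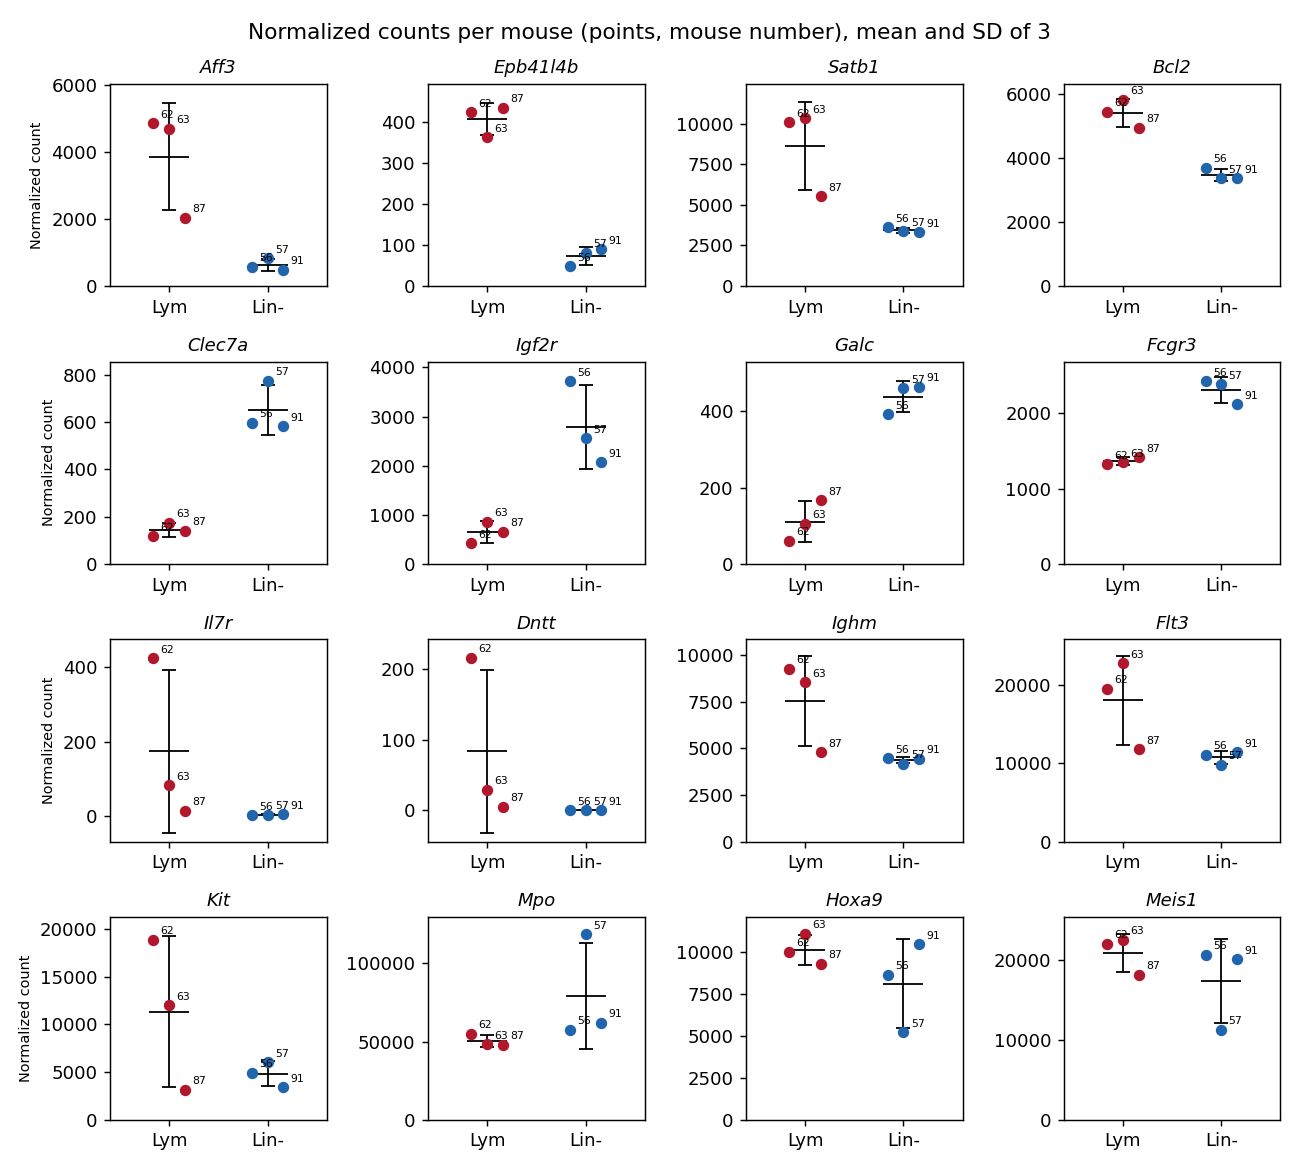
Normalized counts of 16 genes, 1 panel each, with Lym and Lin- on the horizontal axis and the normalized count on the vertical axis. Each point is 1 mouse with its number, the bar is the mean of 3 mice and the whiskers are 1 SD, which reach below 0 for Il7r and Dntt because 1 mouse holds most of the signal. Aff3, Epb41l4b, Satb1 and Bcl2 lie higher in all 3 Lym mice, Clec7a, Igf2r, Galc and Fcgr3 lie higher in all 3 Lin- mice, and Hoxa9 and Meis1 overlap.

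Hoxa9 and Meis1, the genes that define the leukaemia, had overlapping values. Hoxa9 was at 10027, 11116 and 9330 in Lym mice 62, 63 and 87 and 8667, 5224 and 10473 in Lin- mice 56, 57 and 91, with a log2 fold change of 0.38 ± 0.23 (limma adjusted p = 0.581). Meis1 was at 22090, 22600 and 18190 against 20731, 11303 and 20123, with a log2 fold change of 0.31 ± 0.23 (limma adjusted p = 0.635). Reads of an introduced copy and of the endogenous gene would be counted together. Only 4 of the 17 genes of the Hoxa, Meis and Pbx list passed the low-value filter, so the list was not tested, and none of the 4 passed adjusted over the list alone.

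Of the 32 gene lists fixed in advance, 26 had at least 5 tested members, and camera with a preset correlation put 11 past an adjusted p of 0.05, 7 higher and 4 lower in Lym. With the correlation estimated per list none passed, the lowest adjusted p being 0.487, and none passed with fry, the lowest being 0.273. No member of any list passed over all genes tested in limma, so the counts of members given below as adjusted over the list alone stand against 0 over all genes. The authors' calls named here and above were chosen after their values were seen, and so were Adgrg1, Cd79a, Dntt, Ebf1, Gata2, Igll1, Lyz2, Pax5, Prtn3, Rag1, Tcf4 and Vpreb1.

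The early B and lymphoid priming lists passed as higher in Lym by camera with the preset correlation, but not with an estimated one. Il7r was a tested member of both lists and of the interleukin-7 list. The Hoxa9 and Meis1 target list shared Sox4 and Erg with the early B list and Flt3 with the lymphoid priming list. It shared Cd34 and Lmo2 with the stem and progenitor list and Bcl2 with the interleukin-7 list. The lists that passed are thus not separate results. Most members of the early B list, Pax5 and Cd79a among them, were too low to be tested. Of the 10 tested members of the early B list, 8 were higher in Lym (median log2 fold change 1.14, camera adjusted p = 0.000962; adjusted p = 0.487 with an estimated correlation), and 5 members higher and 1 lower passed adjusted over the list alone. Sox4, a transcription factor of progenitor cells, was at 10741, 7010 and 4395 in Lym mice 62, 63 and 87 against 3373, 4155 and 2551 in Lin- mice 56, 57 and 91. Bach2, a transcriptional repressor in B cells, was at 190, 214 and 98.1 against 43.2, 35.2 and 29.9, and Rag2 at 361, 120 and 27.6 against 19.4, 38.7 and 13.4. Reads of the whole list came to 1648, 1237 and 1138 CPM in Lym mice 62, 63 and 87 and to 1117, 1146 and 1100 CPM in Lin- mice 56, 57 and 91, so that mouse 87 lay inside the Lin- range. The surface sialoprotein Spn, present in both groups, was at 13190 ± 2499 against 10990 ± 130 (SD, n = 3 each). The 2 exceptions were Cd24a (-1.22) and Cd79b (-0.53, both log2 fold changes), of which Cd79b was higher without Lym mouse 63 (0.49) and without Lin- mouse 56 (0.082).

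The remaining 16 early B genes fell below the filter on low values, and Pax5 and Cd79a among them were at or near the floor. Pax5, the factor that commits cells to the B lineage, reached at most 0.95 in any library, and Cd79a at most 4.48. Ebf1, an earlier B-lineage factor, was at 59.4, 6.71 and 14.3 in Lym mice 62, 63 and 87 against 0, 1.76 and 0 in Lin- mice 56, 57 and 91. Dntt, the terminal transferase of lymphoid progenitors, was at 216, 29.1 and 4.76 against 0 in all 3 Lin- libraries, with most of its signal in mouse 62. Rag1 was at 104, 2.24 and 1.91 against 0, under the floor of its library in Lym mice 63 and 87. The surrogate light chain genes Vpreb1 (63.9, 12.3 and 0 in Lym against 0, 6.16 and 3.09 in Lin-) and Igll1 (44.9, 1.12 and 6.67 against 0, 1.76 and 0) were likewise highest in mouse 62. The receptor for interleukin-7, Il7r, was at 424, 82.8 and 14.3 in Lym and at 2.65, 3.52 and 4.13 in Lin-, a log2 fold change of 3.96 ± 1.03 (limma adjusted p = 0.420).

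Of 14 tested genes of lymphoid priming, 12 were higher in Lym (median log2 fold change 0.65, camera adjusted p = 0.000131; adjusted p = 0.487 with an estimated correlation), and 10 higher and 1 lower passed adjusted over the list alone. Satb1, a chromatin organizer of lymphoid cells, was at 10092, 10351 and 5525 in Lym mice 62, 63 and 87 against 3630, 3379 and 3321 in Lin- mice 56, 57 and 91, a log2 fold change of 1.27 ± 0.23 (limma adjusted p = 0.406). Runx2 was at 2709 ± 810 against 1419 ± 103 and Tcf4 at 4100 ± 1273 against 2409 ± 264 (SD, n = 3 each). Flt3, a cytokine receptor of multipotent and lymphoid progenitors, was at 19525, 22805 and 11811 against 11129, 9840 and 11410, and Ikzf1, a lymphoid transcription factor, at 10910 ± 984 against 8887 ± 74.0. Ikzf3 (-1.69) and Wfdc17 (-0.40, and 0.029 without Lym mouse 87) were the exceptions by log2 fold change. Reads of the whole list came to 4039, 3821 and 2468 CPM in Lym mice 62, 63 and 87 and to 2381, 2226 and 2206 CPM in Lin- mice 56, 57 and 91, so that mouse 87 lay close above the Lin- range.

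The list of interleukin-7 and JAK-STAT signalling had 17 of 18 tested genes higher in Lym (median log2 fold change 0.53, camera adjusted p = 5.4e-05; adjusted p = 0.487 with an estimated correlation), and 2 passed adjusted over the list alone. Bcl2, an inhibitor of apoptosis, was at 5456, 5824 and 4958 in Lym mice 62, 63 and 87 against 3702, 3377 and 3379 in Lin- mice 56, 57 and 91. Myc was at 7897 ± 2141 against 5406 ± 622 and the kinase gene Jak1 at 5354 ± 1728 against 4103 ± 234 (SD, n = 3 each). Socs1, an inhibitor of this pathway, was the exception (-0.71 on the log2 scale). Genes of MHC class II presentation were higher in 8 of 10 members (median log2 fold change 0.39, camera adjusted p = 0.00725; adjusted p = 0.487 with an estimated correlation), with 1 member past adjusted over the list alone. Reads of the list came to 307.5, 345 and 207 CPM in Lym against 196.5, 224 and 212 CPM in Lin-, with mouse 87 inside the Lin- range. Its most abundant members were H2-DMa, at 1370 ± 200 against 1311 ± 49.2, and the regulator Rfx5, at 1062 ± 66.9 against 860 ± 154. H2-DMb1 (-0.15, and 0.034 without Lym mouse 62) and H2-DMb2 (-0.18, but 0.138 in edgeR with TMM, 0.65 without Lym mouse 62 and 0.104 without Lin- mouse 57) were lower by log2 fold change, and the list's camera adjusted p was 0.0645 without Lym mouse 63.

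Lists of mature B cells, B-cell receptor signalling and plasma cells did not pass. The mature B list had 5 of 7 members higher in Lym (camera adjusted p = 0.127), with 2 past adjusted over the list alone, and passed without Lym mouse 87 (0.0233). Ighm, the constant region of the immunoglobulin mu chain, was at 9260, 8540 and 4798 in Lym mice 62, 63 and 87 against 4471, 4179 and 4456 in Lin- mice 56, 57 and 91, and Tnfrsf13b at 2833 ± 386 against 2190 ± 21.6 (SD, n = 3 each). For B-cell receptor signalling, 12 of 18 members were higher (camera adjusted p = 0.27) and 1, the lower Prkcb, passed adjusted over the list alone. Ptpn6 was at 8375 ± 1498 against 8552 ± 794.5 and Vav1 at 7915 ± 168 against 7074 ± 274. The plasma cell list (camera adjusted p = 0.90) had a median of 0.04 and a mean of 0.21 on the log2 scale while camera placed it lower in Lym. Its one member past adjusted over the list alone was Fkbp11, a chaperone gene at 22.4, 5.59 and 34.3 against 202, 81.0 and 109. Xbp1 was at 3153 ± 575 against 3032 ± 35.3, and Mzb1 at 408, 83.9 and 5.72 against 0, 14.1 and 3.09.

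Few reads fell on variable segments of the immunoglobulin heavy and kappa chains in either group, while joining segments of the heavy chain had more in every library. Variable segments of the heavy chain had 12, 26 and 19 reads in Lym mice 62, 63 and 87 and 7, 3 and 6 reads in Lin- mice 56, 57 and 91, spread over up to 10 of the 185 segments. Those of the kappa chain had 6, 15 and 7 reads against 5, 1 and 3. Olfactory, vomeronasal and other tissue-restricted gene families were also read more widely in Lym, with 111, 337 and 265 of 1610 such genes having a read at 1 depth against 46, 47 and 50, so these few reads on variable segments were not told apart from reads of genomic DNA. Joining segments of the heavy chain had 239, 280 and 73 reads against 62, 159 and 43, and diversity segments 39, 53 and 4 reads against 12, 10 and 0, all on Ighd4-1. Variable segments of the T-cell receptor beta chain had 52, 108 and 9 reads against 22, 105 and 20, and those of the alpha chain 8, 19 and 6 against 2, 3 and 3. At these counts no dominant heavy or kappa chain rearrangement was detectable in any library.

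Stem and progenitor genes were higher in Lym in 9 of 10 members (median log2 fold change 1.00, camera adjusted p = 0.000985; adjusted p = 0.487 with an estimated correlation), with 2 past adjusted over the list alone. Kit, the receptor that was used to select the Lin- cells, was at 18902, 12027 and 3158 in Lym mice 62, 63 and 87 against 4953, 6066 and 3420 in Lin- mice 56, 57 and 91. Gata2, a transcription factor of stem and mast cells, was at 6521, 2938 and 1505 against 1152, 974 and 798. Reads of the stem and progenitor list came to 2492, 1603 and 952 CPM in Lym against 913, 1036 and 882 CPM in Lin-, with mouse 87 inside the Lin- range. Kit and Gata2 are mast cell genes too, and reads of the mast cell, basophil and eosinophil list came to 844, 227 and 45.2 CPM against 45.4, 48.9 and 16.7 CPM. In Lym mice 62 and 63 they were mostly those of Cpa3, the only member of that list past adjusted over the list alone. Cd34 was at 6637 ± 447 against 4935 ± 1096 (SD, n = 3 each), and Lmo2 at 6189 ± 1400 against 5412 ± 118. Cd48 (-0.06, and 0.10 without Lym mouse 87) was the exception. With all mice the limma adjusted p was 0.576 for Kit and 0.42 for Gata2. Without Lym mouse 87 it was 0.00677 and 0.00502, and the stem and progenitor list held 6 calls over all genes. That mouse had the lowest Lym value of both genes, so the fit without it is no separate support. Genes reported as targets of Hoxa9 and Meis1 were higher in 12 of 19 members (median log2 fold change 0.24, camera adjusted p = 0.0285; adjusted p = 0.487 with an estimated correlation), with 1 past adjusted over the list alone. The kinase gene Cdk6 was at 46588, 38810 and 29956 against 25403, 29567 and 29145, and Myb at 33500 ± 8766 against 23760 ± 1994. Its camera adjusted p was 0.0948 without Lym mouse 63, 0.113 without Lin- mouse 57 and 0.204 with no filter on low values. Polycomb genes were higher in 17 of 22 members (median log2 fold change 0.18, camera adjusted p = 0.0492; adjusted p = 0.487 with an estimated correlation), with 0 past adjusted over the list alone. Its most abundant members, the histone-binding proteins Rbbp4 (5174 ± 1044 against 5819 ± 928) and Rbbp7 (4871 ± 860 against 5577 ± 783), were lower in the Lym mean, and the list's camera adjusted p was 0.285 with no filter, 0.0524 with TMM factors, 0.156 without Lym mouse 62, 0.0900 without Lym mouse 87, 0.105 without Lin- mouse 57 and 0.0588 without Lin- mouse 91.

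Of the myeloid lists, 1 passed as lower in Lym by camera with the preset correlation and the others did not pass. Of 16 tested genes of monocytes and macrophages, 13 were lower in Lym (median log2 fold change -0.41, camera adjusted p = 0.00796, and 0.487 with an estimated correlation), with 0 past adjusted over the list alone. Its reads came to 2640, 4404 and 3406 CPM in Lym mice 62, 63 and 87. In Lin- mice 56, 57 and 91 they came to 4532, 4665 and 4053 CPM, so that Lym mouse 63 lay inside the Lin- range. F13a1, a coagulation factor of monocytes, was at 24928, 45787 and 34183 in Lym mice 62, 63 and 87 against 48910, 45993 and 41783 in Lin- mice 56, 57 and 91, and lysozyme (Lyz2) at 1299, 1167 and 858 against 1537, 1809 and 1458. Irf8, a factor of monocyte and dendritic development, was among the 3 members not lower in Lym, at 12300 ± 3145 against 10990 ± 1198 (SD, n = 3 each), beside Ms4a6c (0.28) and Mrc1 (0.35). By log2 fold change Irf8 was lower without Lym mouse 63 (-0.063), and Mrc1 was lower without Lin- mouse 56 (-0.61) and in edgeR with upper-quartile factors (-0.008) or library totals (-0.021). The list's camera adjusted p was 0.0691 with no filter on low values. Granule genes of myeloid progenitors were abundant in both groups and did not pass as a list (camera adjusted p = 0.299, 11 of 18 lower in Lym, 0 past adjusted over the list alone). Myeloperoxidase (Mpo) was at 55058, 48212 and 48014 in Lym against 57600, 118583 and 61987 in Lin-, Calr at 45840 ± 6751 against 47460 ± 2318, and Prtn3, proteinase 3, at 3516 ± 452.5 against 5955 ± 1660. The neutrophil list (camera adjusted p = 0.813) had a median of 0.08 and a mean of -0.13, with Csf3r at 1068 ± 310 against 1150 ± 152 and Cd177 at 527 ± 302 against 890 ± 307. Itgam, which encodes CD11b, was at 597, 552 and 286 against 352, 445 and 321. Myeloid cytokine receptors (camera adjusted p = 0.299; 0.0169 and lower in Lym without Lym mouse 63) and surface antigens of acute myeloid leukaemia (0.579; median -0.02 and mean 0.02) did not pass. Ifngr1 was at 7925 ± 530.5 against 10420 ± 598, Cd47 at 19660 ± 3057 against 16890 ± 279 and Cd93 at 18500 ± 3847 against 17830 ± 1421. Of the surface antigens, Fcgr3, lower in Lym, and 1 gene higher in Lym, Adgrg1 (2.10 on the log2 scale), passed adjusted over the list alone. Ptprc, the pan-leukocyte antigen CD45, was at 7964 ± 1660 against 6236 ± 290.

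The S phase, oxidative phosphorylation and glycolysis lists passed as lower in Lym by camera with the preset correlation of 0.01, through mice 62 and 63. The correlations estimated between their members were 0.854, 0.813 and 0.231, and with these none of the lists passed. Of 37 genes of S phase, 36 were lower (median log2 fold change -0.33, camera adjusted p = 4.51e-06; adjusted p = 0.647 with an estimated correlation), with Rfc2 (0.10, and -0.033 without Lym mouse 62) the exception. Mcm6, a subunit of the replicative helicase, was at 13292, 11576 and 16664 in Lym mice 62, 63 and 87 against 17438, 14103 and 16853 in Lin- mice 56, 57 and 91, and Mcm3 at 9099, 7856 and 12781 against 12313, 10475 and 12278. Reads of the list came to 4898, 4278 and 7288 CPM against 7224, 6074 and 6943 CPM, so that Lym mouse 87 had the highest value of all libraries. Nuclear genes of oxidative phosphorylation were lower in 36 of 37 members (median -0.38, camera adjusted p = 6.92e-09; adjusted p = 0.544 with an estimated correlation), Ndufa4 (0.19) being the exception. Atp5b, a subunit of ATP synthase, was at 8567, 9915 and 13616 against 15193, 12434 and 13961, and Sdha at 5893 ± 585 against 6969 ± 381 (SD, n = 3 each). Glycolysis genes were lower in 17 of 19 members (median -0.38, camera adjusted p = 0.000575; adjusted p = 0.487 with an estimated correlation), with Hk2 (0.13) and Pfkm (0.14) the exceptions. Pkm was at 13111, 14148 and 19295 against 18369, 16734 and 21158, and Gpi1 at 13960 ± 1831 against 14560 ± 1127. None of these lists had a member past adjusted over the list alone. G2 and M phase genes did not pass (camera adjusted p = 0.27, 30 of 47 lower), and passed, lower in Lym, without Lym mouse 87 (5.22e-06), without Lin- mouse 57 (0.00665) and with no filter on low values (0.0263), while camera placed the list higher in Lym without Lym mouse 62 (0.788) and without Lym mouse 63 (0.412). Mki67, a proliferation marker, was at 25019, 24671 and 46231 against 28571, 21068 and 34789, and Top2a at 16220 ± 5154 against 14040 ± 2959. Mitochondrially encoded genes (camera adjusted p = 0.27, 7 of 8 lower) varied most within Lin-, where mt-Co1 was at 21941, 49941 and 50541 against 36512, 35578 and 27778 in Lym, and mt-Nd5 at 14840, 34659 and 33846 against 24038, 23674 and 20750. Without Lin- mouse 56 that list passed, lower in Lym (5.24e-07).

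**Figure D3:**
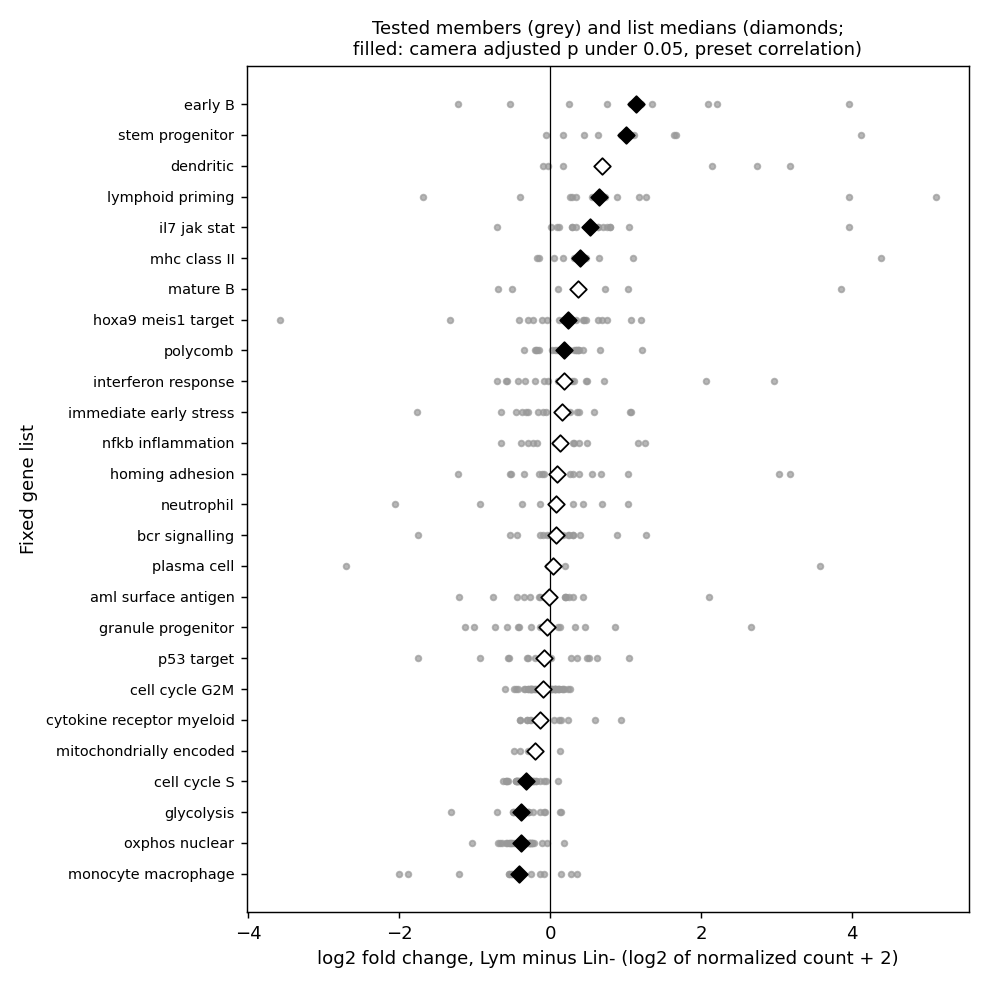
Log2 fold changes, Lym minus Lin-, of the tested members (grey points) and the median (diamond) of the 26 tested gene lists, on the log2(normalized count + 2) scale, 1 list per line. Filled diamonds mark the 11 lists past an adjusted p of 0.05 by camera with the preset correlation, from 1.14 for the early B list to -0.41 for monocytes and macrophages. None of them passed with an estimated correlation.

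Markers of other cell types were measured as well, since a sorted fraction can hold more than 1 type. Cpa3, the mast cell carboxypeptidase, was at 15971, 3966 and 343 in Lym mice 62, 63 and 87 against 196, 147 and 6.19 in Lin- mice 56, 57 and 91, and Hdc at 1345, 498 and 343 against 488, 583 and 100.1. With 4 tested members and 11 below the filter the mast cell list was not tested as a list, and 1 member, Cpa3, passed adjusted over the list alone. Hdc (0.996), Mcpt8 (-0.046) and Ms4a2 (0.436, all log2 fold changes) did not. Megakaryocyte genes had 4 tested members, all higher in Lym, with 2 past adjusted over the list alone, while 10 of the 14 fell below the filter. Itgb3 was at 2993 ± 892 against 1777 ± 61.7 (SD, n = 3 each), and Nrgn at 1028, 684 and 0 against 2.65, 14.1 and 0. Of 17 stromal and endothelial genes 15 fell below the filter. The 2 tested both passed adjusted over the list alone, Pdgfrb at 4174, 3658 and 672 against 663, 705 and 459 and Pecam1 at 8088 ± 1369 against 5519 ± 531. Erythroid genes had 2 tested members and 17 below the filter, with Tfrc at 1738 ± 368 against 1224 ± 253 and Rhd at 19.1 ± 8.80 against 10.4 ± 7.54. With so few members tested, these counts do not show that such cells were present. No T and NK cell gene passed the filter, and reads of the list came to 8.65, 3.78 and 3.05 CPM in Lym against 0.67, 0.66 and 0.65 CPM in Lin-, with Lck at 97.6, 19.0 and 1.91 against 8.82, 0.88 and 5.16 and Cd5 at 0, 15.7 and 18.1 against 1.76, 6.16 and 3.09. Dendritic cell genes did not pass (camera adjusted p = 0.0584, 5 of 7 higher) and passed without Lym mouse 87 (0.00676), with no filter on low values (0.0213) and with a pseudocount of 5 (0.0497), with Cst3 at 2764 ± 116 against 2962 ± 326.

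The 5 remaining lists did not pass. They were interferon response (camera adjusted p = 0.27, 15 of 23 higher in Lym), NF-kB inflammation (0.101, 8 of 13 higher), immediate early stress (0.357, 11 of 20 higher), p53 targets (0.875, 7 of 19 higher) and homing and adhesion (0.342, 11 of 18 higher), with 0 members past adjusted over the list alone in each. The NF-kB list passed without Lym mouse 62 (0.0258) and without Lym mouse 87 (0.0207), and the homing list without Lym mouse 87 (0.0492). For p53 targets the median (-0.09) and mean (-0.09) were below 0 while camera placed the list higher in Lym. The RNA sensor gene Ddx58 was at 209, 69.4 and 37.2 in Lym mice 62, 63 and 87 against 6.18, 22.9 and 4.13 in Lin- mice 56, 57 and 91. Irf9 was at 1095 ± 194 against 884 ± 192, Parp14 at 1885 ± 495 against 1333 ± 123, Nfkb1 at 4507 ± 420 against 3664 ± 140 and Birc3 at 1220 ± 352 against 952 ± 30.0 (SD, n = 3 each). Jun was at 2805 ± 1560 against 3433 ± 1078, Hsp90aa1 at 15330 ± 3267 against 16980 ± 1974, Mdm2 at 1396 ± 39.9 against 1389 ± 92.1 and Ccng1 at 2050 ± 362 against 2565 ± 592. The integrin gene Itga4 was at 19131, 13062 and 10782 in Lym against 9220, 8809 and 8209 in Lin-.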

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

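Alternatives to a fixed choice were set before the data were examined, except edgeR with TMM, pseudocounts of 0.5 and 5 for single genes and of 5 for lists, array weights, robust moderation, the DESeq2 fits with a prior, without filtering or with a mouse left out, and TMM factors for lists, which were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Size factors for lists were not run separately, since the deposited values already carry them. Where a value changed, the cause was not tested.

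The count of 0 limma genes (1459 at an unadjusted p under 0.05) became 215 with DESeq2 (177 higher and 38 lower in Lym), 5 with no filter on low values, 1 with a pseudocount of 5, 660 with array weights (426 higher and 234 lower) and 2 with all libraries thinned to 1 depth. It was 0 with edgeR under TMM, size factors, upper-quartile factors and library totals. Leaving out a mouse gave 0 to 1348, the highest without Lym mouse 87. The DESeq2 count of 215 became 101 with a prior and without filtering, and 53 to 2080 with a mouse left out, the lowest without Lym mouse 63 and without Lin- mouse 56, and the highest without Lym mouse 87. The authors' calls found here rose from 0 in limma to 101 in DESeq2. The first component held 49.5% of the variance over all genes tested. Between scalings the median of all genes moved from -0.0117 to -0.0533 on the log2 scale.

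Of 2167 values for 116 named genes under the alternatives, 1974 kept direction and side of the threshold, 144 passed it and 49 reversed, in 24 genes. Of those that passed, 54 did so without Lym mouse 87, 47 with array weights and 36 with DESeq2. With array weights the log2 fold change became 0.044 for Cd48, 0.088 for H2-DMb1, 0.358 for H2-DMb2, 0.003 for Jun, -0.132 for Mki67, -0.419 for Mrc1, -0.049 for Rfc2, -0.056 for Top2a and 0.235 for Wfdc17. H2-DMb2 was at 0.138 in edgeR with TMM, 0.138 with size factors, 0.135 with upper-quartile factors, 0.102 with library totals and 0.137 in DESeq2. Mrc1 was at -0.008 with upper-quartile factors and -0.021 with library totals, where Mdm2 was at -0.034.

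With a mouse left out, log2 fold changes ran from -0.161 to 0.054 for Calr, -0.173 to 0.104 for Cd48, -1.478 to 0.494 for Cd79b, -0.116 to 0.185 for Cd93, -4.647 to 0.547 for Ddx3y, -0.139 to 0.046 for Gpi1, -0.012 to 0.181 for H2-DMa, -0.387 to 0.034 for H2-DMb1, -0.725 to 0.649 for H2-DMb2 and -0.063 to 0.248 for Irf8. They ran from -0.187 to 3.626 for Kdm5b, -4.088 to 0.659 for Kdm5d, -0.007 to 0.281 for Lmo2, -0.029 to 0.062 for Mdm2, -0.15 to 0.317 for Mki67, -0.609 to 0.95 for Mrc1, -0.157 to 0.105 for Ptpn6, -0.033 to 0.217 for Rfc2, -0.059 to 0.348 for Top2a, -4.198 to 0.501 for Uty, -0.858 to 0.029 for Wfdc17, -0.087 to 0.18 for Xbp1 and -0.589 to 0.023 for mt-Nd5.

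Of the 11 lists past the threshold by camera, 0 passed with an estimated correlation and 0 with fry. The adjusted p with an estimated correlation was 0.487 for the early B, lymphoid priming, stem and progenitor, Hoxa9 and Meis1 target, monocyte and macrophage, MHC class II, interleukin-7, glycolysis and polycomb lists, 0.647 for S phase and 0.544 for oxidative phosphorylation. With fry it was 0.273 for the early B, lymphoid priming, Hoxa9 and Meis1 target, MHC class II, interleukin-7, glycolysis and polycomb lists, 0.334 for stem and progenitor genes, 0.331 for the monocyte and oxidative phosphorylation lists and 0.489 for S phase. With no filter the adjusted p was 0.204 for Hoxa9 and Meis1 targets, 0.0691 for monocytes, 0.285 for polycomb genes, 0.0213 for dendritic cells and 0.0263 for G2 and M phase, and the direction reversed for the neutrophil (0.399) and p53 target (0.591) lists. Polycomb genes were at 0.0524 with TMM factors, and dendritic genes at 0.0497 with a pseudocount of 5.

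With a mouse left out, camera adjusted p-values ran from 0.0233 to 0.278 for mature B, 0.0164 to 0.113 for Hoxa9 and Meis1 targets, 0.428 to 0.973 for neutrophil, 0.00676 to 0.144 for dendritic, 0.00362 to 0.0645 for MHC class II, 0.0169 to 0.874 for myeloid cytokine receptor, 0.186 to 0.656 for leukaemia surface antigen, 5.22e-06 to 0.856 for G2 and M phase, 0.0665 to 0.973 for interferon response, 0.0207 to 0.736 for NF-kB, 0.121 to 0.766 for immediate early stress, 0.486 to 0.559 for p53 target, 5.24e-07 to 0.856 for mitochondrially encoded, 0.0181 to 0.156 for polycomb and 0.0492 to 0.665 for homing genes. The neutrophil, leukaemia surface antigen, G2 and M phase, interferon, immediate early stress and p53 target lists changed direction in at least 1 of these fits. At the depth here Pax5, at most 0.95, was under the floor of 3 reads in every library, so no fold change is given for it.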

Other observations

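The tests of other splits, of the genes shared by mice 87 and 91, of genomic DNA in the Lym libraries and of a Lin- library prepared like the others were chosen after the result was seen. Some genes well above the floor in most libraries were at or near 0 in others. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 0 in Lym mouse 63, where 14 reads fell on Y genes against 2698 to 5991 in the other 5 libraries, and Xist had 2 reads there. Eif2s3y (chromosome Y, 1010543 to 1028847) was at 0 in Lym mouse 87 and at 1.03 in Lin- mouse 91, and at 1133, 1136 and 582 in Lym mouse 62 and Lin- mice 56 and 57. Its neighbours were present in mice 87 and 91, Kdm5d (897788 to 956786) at 1025 and 1026 and Uty (1096861 to 1245759) at 705 and 855.

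Of the 10 splits of the 6 libraries into groups of 3, the real one gave 0 genes in limma and the highest other 71. With DESeq2 the real split gave 215 and the highest other 1260, and 2 of the 10 gave as many as the real one. For lists the real split gave 11 and the highest other 12, again 2 of 10 giving as many. With a real limma count of 0, all 10 splits give as many by construction, which says nothing. The splits are too few for a share under 0.05. The split of Lym mice 62 and 63 with Lin- mouse 57 gave the 71 and the 1260. Lym mice 62 and 63 with Lin- mouse 56 or 91 gave 0 in limma, and 73 and 10 in DESeq2. The cause was not tested.

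The Lym library of mouse 87 lay nearer the Lin- libraries than the other Lym libraries, and depth is argued against, since at 1 depth its lowest correlation with a Lin- library was 0.965 and its highest with a Lym library 0.948. A Lin- library under a Lym label stays open. At 151 genes chosen without mouse 87, its median position was 0.046 on a scale of normalized counts from the Lin- mean (0) to the other Lym mice (1). Lin- libraries held out of that mean, but not out of the choice of genes, lay at -0.082 to 0.097. But the median of mouse 87 was 0.016 at the 94 genes higher in Lym and 0.235 at the 57 lower ones, where held-out Lin- libraries lay at -0.251 to 0.204. Among its highest positions, Epb41l4b (1.128), Clec7a (1.009) and Igf2r (0.991) lay at the Lym end. Genes were also chosen anew without each of Lin- mice 56, 57 and 91 (296, 1525 and 330 genes), with positions on the log2 scale. The median position of mouse 87 was then 0.156, 0.122 and 0.124, against 0.043, 0.302 and -0.072 for the Lin- library left out. Scale and genes both differ from the first positions. A Lin- library under a Lym label, prepared like the 3 Lin- libraries, is argued against, since at 1 depth 265 silent genes had a read in mouse 87, against at most 50 in a Lin- library. 1 share of Lin- like cells in the sort, which needs 1 position for all genes, stays open too, with an interquartile range of 0.263 against 0.23 for the widest held-out Lin- library but those unlike medians and genes from Cpa3 (0.023) to Clec7a, and a difference in this mouse's leukaemia stays open and untested.

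Lym mouse 87 and Lin- mouse 91 shared 11 genes set apart at least 10-fold from the other 4 libraries, among them Kdm5b at 22.9 and 6.19 against 278 to 1589. Cells of 1 founder leukaemia in both mice may explain this, since the other 8 pairs of a Lym with a Lin- library had at most 1. Whether differences between founders alone set the group difference cannot be told apart from a difference between the groups. Of 330 genes chosen from the other 4 mice, 72.4% kept their direction between mice 87 and 91. About 50% was predicted for founders alone, and over 75% was set to exclude them. Among the 145 larger changes, a part not set beforehand, 76.6% did. The median log2 change fell from 1.74 to 0.33 in the genes higher in Lym and went from -1.68 to -0.19 in the lower ones. Genes vary together, so 50% has no known spread. These 330 genes are those chosen without Lin- mouse 91 above. For the genes chosen without Lin- mouse 56 or 57, mouse 87 lay further toward the other Lym mice than that mouse in 65.9% and 33%. The share thus depends on which Lin- mouse is compared.

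Reads on silent gene families were more widespread in Lym, and Gm10800, a satellite-like gene model, was at 483, 1167 and 886 in Lym against 15.9, 21.1 and 2.06 in Lin-. At 1 depth 111, 337 and 265 of 1610 receptor and structural genes had a read in Lym mice 62, 63 and 87, against 46, 47 and 50 in Lin- mice 56, 57 and 91, a ratio of means of 4.99, and genomic DNA in the Lym libraries may explain this. Of the 81 genes the authors called higher in Lym, 3 satellite-like models, Gm10800 among them, were left out of a further test, and genomic DNA as their source stays open. For the other 78 it is argued against as the source, since its density gave a median of 0.158% of their increase, and at most 4.65%. Differences in cell handling or in the cells themselves stay open and untested.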
